A study of Oryza sativa Indica Group and Oryza sativa Japonica Group with 12 samples.

How the data were processed

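RNA was measured in whole rice seedlings at germination stage, in 12 libraries, with 3 for each combination of variety (CH891 or 02428) and treatment (cadmium chloride at 200 mg/L or distilled water, 3 days). The deposited values are FPKM per gene, per the file headers, in a table of 38332 genes. Per the submitters' processing notes, HISAT and the genome build IRGSP-1.0 were used. The HISAT version and the programs that assembled genes and computed FPKM are not given in the sources used here. Of the genes, 33385 carry 1 locus name of the MSU rice annotation, 1220 carry several and 3727 none, and 2186 locus names occur on more than 1 gene. Genes are named by locus and by the table's description, since it gives no symbols. Descriptions, GO terms, KEGG pathways and enzyme numbers come from the same table. Positions are not given, as no genome was used here. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

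FPKM adjusts for gene length and library size and holds no read counts, so no count model was used. Low values step by the worth of 1 read, and comparing low genes gave depths of 0.953 to 1.34 relative to 02428 control replicate 1. Cadmium libraries lay between 1.18 and 1.34 and controls between 0.953 and 1.14. Exact zeros can be failed estimates. Of genes reaching 5 FPKM in a library of a group, 3.62% to 4.73% were listed at 0 in another library of it. Genes listed at 0 throughout a group are given per library in the report, with no fold. Fitted log2 differences of 3 such genes, given where the varieties are compared gene by gene, count each 0 as a value.

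Values were analysed as log2(FPKM + 1) for genes with FPKM of at least 1 in at least 3 of the 12 libraries, which left 21326. Models were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups, a shared spread and eBayes with a trend. Contrasts were cadmium against control in each variety, the difference of these 2, and CH891 against 02428 within each treatment. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold differences stated without log2 are ratios of mean FPKM.

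The design, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Of 34 lists, 29 were defined by description, and 28 of these had at least 3 tested members. The list of UDP-glycosyltransferases in its fixed spelling had too few, and 5 lists of locus identifiers of another annotation could not be matched to the table. From the annotation 8 further lists were made afterwards. Lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, adjusted over the lists. KEGG pathways with at least 10 tested genes, 130 in all, were tested likewise, a choice made after the data were seen.

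The rule named, for each cadmium comparison and the difference, the 8 largest rises and 8 largest falls with adjusted p under 0.05, a mean of at least 5 FPKM in a compared group, groups that do not overlap and an informative description. Overlap was not asked of the difference. It named 4 and 4 for each variety contrast, and per list the 2 largest rises and falls in each variety. The text describes only part of the genes so named. That part was chosen after their values were seen, with preference for calls that held without each library in turn, so the named genes are more stable than the whole. Of all 143 calls of named genes, 80 held under every alternative run on them, 93 held under every one of these other than leaving out a library, and 0 reversed. The alternative on fold change was not run on named genes. Fits of only the groups compared do not cover the difference, and a gene dropped by a filter was not counted as lost. Phytochelatin synthases were named whatever their values. The rule also named 4 metal transporters by symbol, which could not be matched by symbol, as the table gives none. LOC_Os06g48720, LOC_Os07g15370 and LOC_Os03g46470 were chosen after the values were seen. LOC_Os07g12900 was looked up with them, and no values of it are given here. The sources used here do not link these loci to the symbols of the rule.

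Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, replicate number as a block, eBayes without a trend, a fit of only the groups compared, a fold change of at least 2, and leaving out each library. The steps were tested on simulated data with 200 of 21326 genes changed. In CH891, log2 changes of 1, 2 and 3 were recovered for 20.5%, 81% and 87.5% of them, and in 02428 for 30.5%, 78.5% and 93%, with 3 to 15 false calls. The changed genes were drawn from those with a control mean log2(FPKM + 1) of at least 2. Noise was independent between genes and libraries. So these numbers do not cover low genes, shifts of a whole library or correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.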

Results

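Rice seedlings of 2 varieties were germinated with or without cadmium, and RNA from whole seedlings was sequenced. CH891 is an Indica variety, named in the series as the more cadmium-sensitive of the pair, and 02428 is a Japonica variety. Dishes of 30 germinated seeds received cadmium chloride at 200 mg/L or distilled water, under 16 h of light at 28 °C and 8 h of dark at 25 °C. Seedlings were collected after 3 days, with 3 libraries for each variety and treatment and 12 in all. The labels do not say whether the libraries of a group came from separate dishes, so p-values measure only the spread between these libraries, which may be technical. Expression values were FPKM, whose totals ran from 267758 to 356959 per library, and 21326 of 38332 listed genes passed the filter on low values. Levels are given as mean ± SD of FPKM (n = 3 libraries), and fold changes as differences of log2(FPKM + 1) ± SE, a scale that understates the change of low genes. The depth behind the values is unknown beyond the relative depths of the libraries.

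The libraries divided mainly by variety. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.860 to 0.909 within groups and 0.733 to 0.795 between varieties. CH891 control replicate 1 stood apart, with the lowest FPKM total (267758) and a median log2 value of 2.15 against 2.47 to 2.72 in the other libraries. Its 2 most abundant genes held 8.22% of its total, against 1.58% to 3.03% in the other libraries.

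Cadmium-treated CH891 seedlings were compared with CH891 controls to find the response of the sensitive variety. The metallothionein LOC_Os12g38300, of a family of cysteine-rich metal-binding proteins, stood at 332 ± 40.7 FPKM with cadmium and 17.9 ± 11.7 without (log2 fold change 4.37 ± 0.61, adjusted p = 0.00253). Cytochrome P450 72A1 LOC_Os01g43774 rose from 0.473 ± 0.0913 to 63.1 ± 30.1 FPKM (log2 fold change 5.31 ± 0.33, adjusted p = 3.83e-05). The 12-oxophytodienoate reductase LOC_Os06g11210, of a family with members in jasmonate synthesis, rose 24.4-fold to 117 ± 57.1 FPKM (adjusted p = 0.000983). Glutathione S-transferase GSTU6 LOC_Os10g38600, of a family that joins glutathione to reactive compounds, rose from 0.532 ± 0.335 to 29.4 ± 12.8 FPKM (adjusted p = 8.94e-05). In limma with Benjamini-Hochberg adjustment 982 genes passed the threshold, 920 higher and 62 lower with cadmium. They were 4.60% of all tested genes. A list with a share called near this, or with few falls, therefore does not stand out from all genes.

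**Figure D1:**
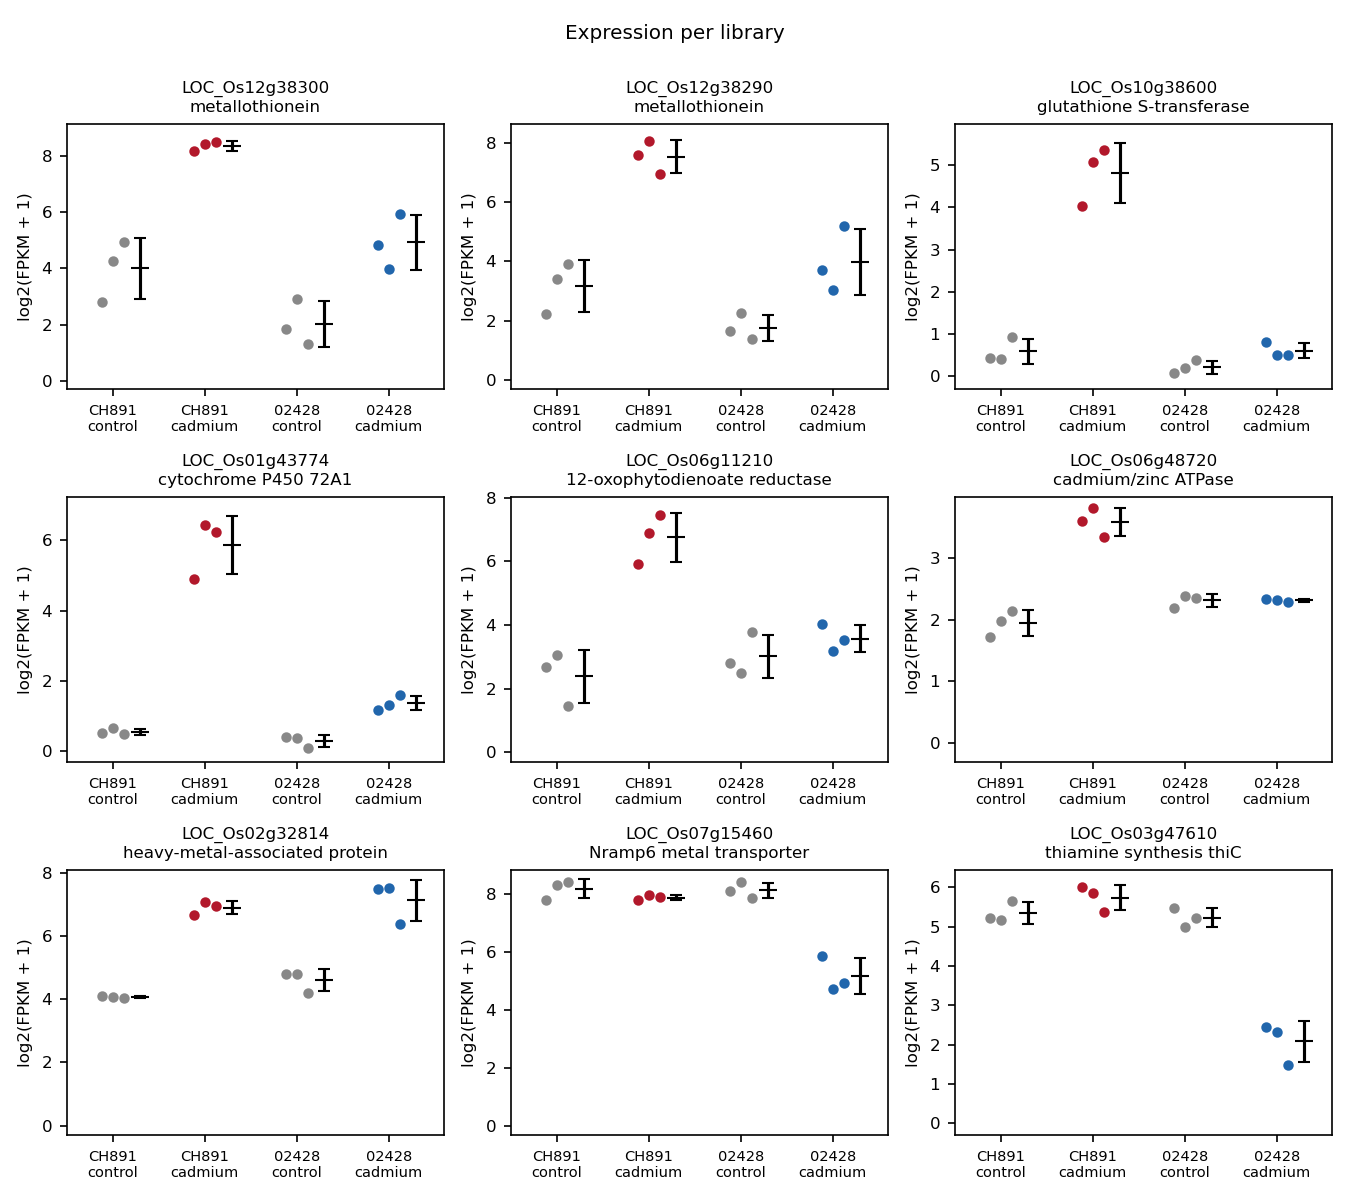
Expression of 9 genes in log2(FPKM + 1) for each library of the 4 groups, with points for libraries and a black mark with a bar for the mean and SD of 3 libraries. LOC_Os12g38300 averaged 332 FPKM in CH891 with cadmium and 17.9 without, and LOC_Os07g15460 averaged 37.5 FPKM in 02428 with cadmium and 283 without.

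Among metallothioneins of CH891, 4 of 9 tested members rose and 0 fell (4 up and 0 down adjusted over the list alone). LOC_Os12g38290 rose 21.3-fold to 192 ± 70.9 FPKM. Camera placed the list above other genes (adjusted p = 6.71e-06, and adjusted p = 0.249 with an estimated correlation). LOC_Os12g38290 and LOC_Os12g38300, and the P450 pair LOC_Os01g43750 and LOC_Os01g43774, are neighbours of the same family that may share reads, so the value of each copy is uncertain. For glutathione and phytochelatin synthesis, 2 of 10 tested members rose and 0 fell (4 up and 0 down adjusted over the list alone). The 2 phytochelatin synthases did not pass the test, with log2 fold changes of -0.10 ± 0.19 for LOC_Os05g34290 (adjusted p = 0.867) and 0.35 ± 0.17 for LOC_Os06g01260 (adjusted p = 0.349). Of the glutathione S-transferases, 7 of 47 tested members rose and 1 fell (14 up and 2 down adjusted over the list alone). LOC_Os01g72150 rose from 0.309 ± 0.08499 to 21.9 ± 13.1 FPKM, and LOC_Os03g04240 fell from 48.9 ± 6.68 to 14.1 ± 3.71 FPKM. Sulfate uptake and assimilation had 4 up and 1 down of 34 (7 up and 1 down adjusted over the list alone). The sulfate transporter LOC_Os03g09970 rose from 0.124 ± 0.0867 to 4.84 ± 3.12 FPKM, and the cysteine synthase LOC_Os02g12900 from 0.278 ± 0.0896 to 3.43 ± 1.32. The serine acetyltransferase LOC_Os05g45710, an enzyme type that makes the precursor of cysteine, was listed at 0 in the 3 cadmium libraries and at 4.52, 11.1 and 12.2 FPKM in the controls (adjusted p = 0.000407). In other fits the number of glutathione and phytochelatin synthesis genes called was 0 without CH891 control replicate 1 or 2 or CH891 cadmium replicate 2 or 3 and 1 without CH891 cadmium replicate 1. For sulfate genes it was 3 without CH891 cadmium replicate 2 or 3.

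Cadmium/zinc-transporting ATPase LOC_Os06g48720, chosen after its values were seen, rose in CH891 from 2.86 ± 0.561 to 11.04 ± 1.89 FPKM (log2 fold change 1.64 ± 0.16, adjusted p = 0.000395). The heavy metal-associated domain gene LOC_Os02g32814 rose 7.51-fold to 119 ± 16.6 FPKM (adjusted p = 0.000596), and the metal cation transporter LOC_Os01g74110 rose 5.85-fold (adjusted p = 0.00372). The cation efflux gene LOC_Os05g03780 fell from 22.8 ± 4.35 to 3.18 ± 1.69 FPKM (adjusted p = 0.0257). That call was lost without any 1 of the 6 CH891 libraries (adjusted p = 0.0926 without CH891 cadmium replicate 1, 0.0724 without CH891 cadmium replicate 2, 0.0602 without CH891 cadmium replicate 3, 0.0615 without CH891 control replicate 1, 0.0853 without CH891 control replicate 2 and 0.0646 without CH891 control replicate 3). LOC_Os07g15370 and LOC_Os03g46470, also metal transporters chosen after the values were seen, had log2 fold changes of 0.51 ± 0.16 (adjusted p = 0.119) and -0.71 ± 0.61 (adjusted p = 0.65). Further lists were drawn from the annotation after the table was seen. Metal ion transport had 7 up and 2 down of 47 (10 up and 2 down adjusted over the list alone) and was placed up (adjusted p = 0.00574, and adjusted p = 0.575 with an estimated correlation). Genes annotated as responding to cadmium ion had 17 up and 0 down of 196 (29 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 0.003, and adjusted p = 0.659 with an estimated correlation). Iron transport and homeostasis had 4 up and 0 down of 35 (6 up and 1 down adjusted over the list alone). Heavy metal-associated domain proteins had 1 up and 0 down of 40 (3 up and 0 down adjusted over the list alone). Terpene synthases had 1 up and 0 down of 14 (2 up and 0 down adjusted over the list alone). UDP-glycosyltransferases had 3 up and 0 down of 37 (3 up and 0 down adjusted over the list alone). Fermentation enzymes by enzyme number, among which the annotation puts phytochelatin synthases, had 1 up and 0 down of 17 (2 up and 0 down adjusted over the list alone). In other fits, metal ion transport genes called numbered 4 without CH891 cadmium replicate 3 and 5 without CH891 cadmium replicate 1 or 2. Genes responding to cadmium ion called numbered 10 without CH891 cadmium replicate 2. Iron transport genes called numbered 1 without CH891 cadmium replicate 2 and 2 without CH891 cadmium replicate 1 or 3.

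Class III peroxidases of CH891, secreted haem enzymes, had 14 up and 0 down of 84 (24 up and 1 down adjusted over the list alone) and were placed up (adjusted p = 0.00785, and adjusted p = 0.249 with an estimated correlation). Among them LOC_Os07g48010 rose from 1.74 ± 0.253 to 28.8 ± 21.4 FPKM. Antioxidant enzymes had 4 up and 2 down of 43 (6 up and 6 down adjusted over the list alone). The peroxiredoxin LOC_Os07g44440 rose 11.2-fold, and LOC_Os08g36630, described as a monodehydroascorbate reductase and carbonic anhydrase, rose 3.997-fold. Pathogenesis-related proteins had 5 up and 0 down of 48 (8 up and 0 down adjusted over the list alone), with the chitinase LOC_Os05g33130 16.7-fold higher and the Bet v I family gene LOC_Os12g36850 16.9-fold higher. The wound-induced protein gene LOC_Os11g37950 rose 25.3-fold to 78.7 ± 34.1 FPKM (adjusted p = 0.000522). Phenylpropanoid and lignin synthesis had 5 up and 1 down of 32 (7 up and 2 down adjusted over the list alone). The laccase LOC_Os11g42200 rose by 3.51 ± 0.43 on the log2 scale, and the laccase LOC_Os05g38410 fell by 1.36 ± 0.18. Jasmonate synthesis and signalling had 7 up and 0 down of 21 (7 up and 0 down adjusted over the list alone) and was placed up (adjusted p = 0.0164, and adjusted p = 0.398 with an estimated correlation). Left-out libraries ended the call of class III peroxidases (adjusted p = 0.0635 without CH891 cadmium replicate 1, 0.0682 without CH891 control replicate 2 and 0.0835 without CH891 control replicate 3) and that of jasmonate (adjusted p = 0.318 without CH891 cadmium replicate 1, 0.0789 without CH891 cadmium replicate 2, 0.12 without CH891 cadmium replicate 3 and 0.0756 without CH891 control replicate 3). Ethylene synthesis had 2 up and 0 down of 16 (2 up and 0 down adjusted over the list alone), with the 1-aminocyclopropane-1-carboxylate oxidase homolog LOC_Os04g10350 3.51-fold higher. Heat shock proteins and factors had 4 up and 0 down of 102 (4 up and 0 down adjusted over the list alone), with the DnaJ gene LOC_Os03g56540 12.7-fold higher and the mitochondrial 22 kDa gene LOC_Os02g52150 5.43-fold higher. Fewer pathogenesis-related proteins were called in several fits (2 without CH891 control replicate 1 or 3, CH891 cadmium replicate 2, 02428 control replicate 2 or 02428 cadmium replicate 3 and 3 without CH891 control replicate 2, CH891 cadmium replicate 3, 02428 control replicate 1 or 02428 cadmium replicate 1), and fewer phenylpropanoid genes (2 without CH891 cadmium replicate 2, 3 without CH891 control replicate 2 or 3 or CH891 cadmium replicate 1, 3 with median-ratio scaling and 3 with quantile normalization). Class III peroxidases called numbered 8 without CH891 cadmium replicate 2. Jasmonate genes called numbered 4 without CH891 cadmium replicate 2 or 3. Ethylene genes called numbered 1 without CH891 cadmium replicate 2, 1 with median-ratio scaling and 1 with quantile normalization. Antioxidant enzymes called numbered 3 without CH891 cadmium replicate 2 and 10 with median-ratio scaling.

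WRKY factors of CH891, a plant family of transcription factors, had 8 up and 0 down of 62 (9 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 0.0401, and adjusted p = 0.635 with an estimated correlation). WRKY1 LOC_Os01g14440 rose from 2.99 ± 0.957 to 13.3 ± 4.39 FPKM, and WRKY72 LOC_Os11g29870 rose 9.55-fold. NAC factors had 9 up and 1 down of 61 (13 up and 2 down adjusted over the list alone) and were placed up (adjusted p = 0.00288, and adjusted p = 0.635 with an estimated correlation). LOC_Os05g10620 rose 3.29-fold, while NAC67 LOC_Os07g12340 was listed at 0 in the 3 cadmium libraries and at 14.8, 19.98 and 24.6 FPKM in the controls. ABC transporters, membrane pumps driven by ATP, had 12 up and 0 down of 41 (19 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 1.62e-05, and adjusted p = 0.635 with an estimated correlation), with the MDR-like member LOC_Os01g50160 8.12-fold higher at 16.5 ± 3.805 FPKM. Cytochrome P450s, oxidising enzymes, had 29 up and 0 down of 142 (46 up and 1 down adjusted over the list alone) and were placed up (adjusted p = 3.04e-08, and adjusted p = 0.249 with an estimated correlation). A second 72A1 gene, LOC_Os01g43750, rose from 0.353 ± 0.131 to 21.5 ± 10.7 FPKM. The calls of WRKY factors (adjusted p = 0.0531 without CH891 cadmium replicate 1, 0.078 without CH891 cadmium replicate 2, 0.0682 without CH891 control replicate 2 and 0.0795 without CH891 control replicate 3) and NAC factors (adjusted p = 0.0521 without CH891 cadmium replicate 1) ended without single libraries. Without CH891 control replicate 1, the library that stood apart, 19 P450s, 10 ABC transporters, 6 NAC and 5 WRKY factors rose. Called P450s numbered 17 without CH891 cadmium replicate 2, 18 without CH891 cadmium replicate 3 and 19 without CH891 control replicate 1. ABC transporters called numbered 5 without CH891 cadmium replicate 2 and 6 without CH891 cadmium replicate 3. NAC factors called numbered 4 without CH891 cadmium replicate 2 or 3. WRKY factors called numbered 4 without CH891 cadmium replicate 2, 5 without CH891 cadmium replicate 3 and 5 with quantile normalization. Without CH891 control replicate 1, 14 class III peroxidases, 7 jasmonate genes and 4 metallothioneins rose.

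Photosynthetic light reactions, the marker list of green tissue, had 1 up and 0 down of 47 (0 up and 0 down adjusted over the list alone) in CH891. Camera placed them below other genes (adjusted p = 0.00258, and adjusted p = 0.635 with an estimated correlation), with a median log2 fold change of -0.22 and a mean of 0.09. Histones had 0 up and 0 down of 41, with 3 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone) and were placed down (adjusted p = 0.0067, and adjusted p = 0.635 with an estimated correlation). Cytosolic ribosomal proteins had 0 up and 0 down of 111, with 1 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone) and were placed down (adjusted p = 0.0401, and adjusted p = 0.829 with an estimated correlation), with a median of 0.02, or -0.17 under median-ratio scaling, and a mean of -0.03. These 3 downward calls ended under quantile normalization (adjusted p = 0.135, 0.0779 and 0.135). Light reactions lost their call when 1 library was left out (adjusted p = 0.0993 without CH891 cadmium replicate 3), as did histones (adjusted p = 0.0521 without CH891 cadmium replicate 1). Ribosomal proteins lost theirs more often (adjusted p = 0.96 without CH891 cadmium replicate 1, 0.0789 without CH891 cadmium replicate 2, 0.344 without CH891 control replicate 2 and 0.0835 without CH891 control replicate 3) and were placed up without CH891 cadmium replicate 1. Carbon fixation had 0 up and 0 down of 10, with 3 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone), and DNA replication and mitosis, the marker list of dividing cells, 0 up and 0 down of 33, with 1 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone). Proteasome subunits had 0 up and 0 down of 33, with 4 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone). Aquaporins had 0 up and 0 down of 24, with 4 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone). Expansins and xyloglucan enzymes had 1 up and 0 down of 29 (5 up and 2 down adjusted over the list alone). Cellulose synthases had 2 up and 0 down of 33 (3 up and 0 down adjusted over the list alone). Starch mobilisation had 1 up and 0 down of 12 (1 up and 0 down adjusted over the list alone). Seed storage proteins, a list made up mostly of lipid transfer proteins, had 4 up and 1 down of 79 (6 up and 2 down adjusted over the list alone). Its member LOC_Os10g40420 was listed at 0 with cadmium and at 12.7, 10.2 and 9.74 FPKM in controls. Storage proteins without lipid transfer proteins, listed afterwards, had 0 up and 0 down of 3, with 2 at an unadjusted p under 0.05 (1 up and 0 down adjusted over the list alone). Nitrogen uptake and assimilation had 2 up and 0 down of 16 (3 up and 0 down adjusted over the list alone), with the nitrite reductase LOC_Os05g42350 3.69-fold higher. LEA proteins, dehydrins and abscisic acid genes had 1 up and 0 down of 22 (3 up and 0 down adjusted over the list alone). In other fits, cellulose synthases called numbered 0 without CH891 cadmium replicate 2, 1 without CH891 control replicate 1 or 2, CH891 cadmium replicate 1 or 3, 02428 control replicate 1 or 3 or 02428 cadmium replicate 1 or 3 and 1 with quantile normalization. Seed storage proteins called numbered 2 without CH891 control replicate 3 or CH891 cadmium replicate 3 and 3 without CH891 cadmium replicate 1. Nitrogen genes called numbered 1 without CH891 control replicate 1 or 2 or CH891 cadmium replicate 2. Lists of CH891 or 02428 with 0 or 1 members called moved by at most 2 members with 1 library left out or another scaling, and the 1 light reaction gene called in CH891 was not called in 9 of 12 fits without 1 library, CH891 control replicate 1 among them.

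With an estimated correlation, camera called 0 lists in CH891 (3 at an unadjusted p under 0.05), and fry, which asks whether members move one way on balance, called 12. Fry does not set members against other genes, so a shift of all genes can add to its calls. It was run only on FPKM as deposited. Glutathione S-transferases and pathogenesis-related proteins were placed up under both scalings (adjusted p = 0.0375 and 0.0319 with median-ratio scaling). Metallothioneins, ABC transporters and P450s were the lists called in each fit without 1 library. Lists called with a library left out, and not with all, were glutathione S-transferases (adjusted p = 0.0372 without CH891 control replicate 1), pathogenesis-related proteins (adjusted p = 0.0355 without CH891 cadmium replicate 2 and 0.0372 without CH891 control replicate 1), phenylpropanoid genes (adjusted p = 0.0394 without CH891 cadmium replicate 3 and 0.0412 without CH891 control replicate 1) and glutathione synthesis (adjusted p = 0.0365 without CH891 cadmium replicate 3). Starch mobilisation (adjusted p = 0.0172 without CH891 cadmium replicate 3) and carbon fixation, placed down (adjusted p = 0.0159 without CH891 cadmium replicate 1 and 0.0248 without CH891 control replicate 3), were others. Camera called 5 lists without CH891 cadmium replicate 1, against 10 with it. Of uncalled lists, heat shock proteins (median 0.11) and DNA replication (median 0.09) were placed down with a positive median and mean, though their medians turned to -0.04 and -0.06 under median-ratio scaling. Antioxidant enzymes (median -0.06, mean 0.07) and terpene synthases (median -0.04, mean 0.05) were placed down with a positive mean. The median change of all genes was 0.11, and -0.02 under median-ratio scaling, where 763 genes were higher and 280 lower. Quantile normalization gave 683 higher and 263 lower. The count of 982 was 393 without CH891 cadmium replicate 2, 449 without CH891 cadmium replicate 3, and 754 (614 higher and 140 lower) without CH891 control replicate 1.

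**Figure D2:**
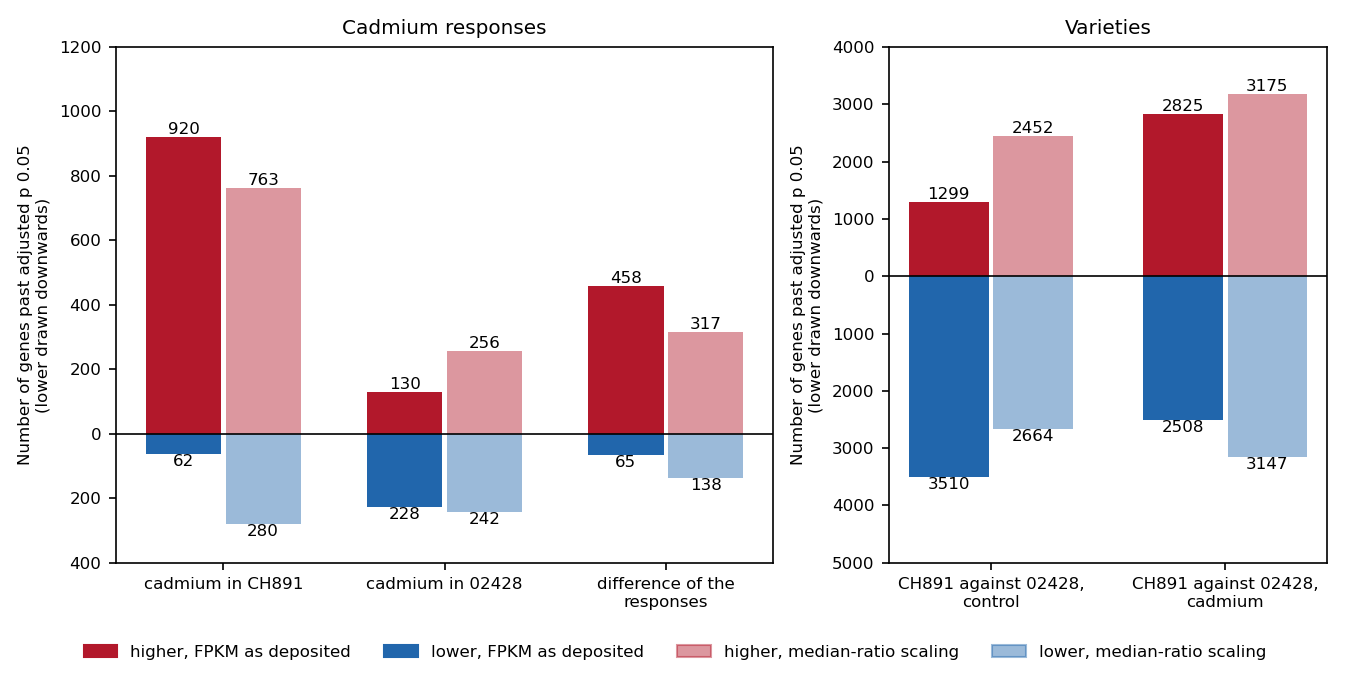
Number of genes past adjusted p 0.05 in each comparison, higher drawn upwards and lower downwards, for FPKM as deposited (dark) and after median-ratio scaling (light). CH891 gave 920 higher and 62 lower genes as deposited and 763 and 280 after scaling. For 02428 the numbers were 130 and 228 as deposited and 256 and 242 after scaling, a near-even split.

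Cadmium-treated 02428 seedlings were compared with their own controls in the same way. The metal transporter LOC_Os07g15460 fell from 283 ± 51.9 to 37.5 ± 17.7 FPKM (log2 fold change -2.96 ± 0.30, adjusted p = 0.000868). The annotation describes it as Nramp6, which is not given as a rice symbol. The thiamine synthesis gene thiC, LOC_Os03g47610, fell 10.7-fold to 3.41 ± 1.42 FPKM (adjusted p = 0.000375). LOC_Os07g34570, an FAD-dependent oxidoreductase that the annotation also ties to thiamine synthesis, fell from 712 ± 392 to 33.7 ± 0.659 FPKM (adjusted p = 0.000304). The MYB factor LOC_Os08g06110, in the circadian rhythm pathway of the annotation, rose 8.04-fold to 142 ± 13.1 FPKM (log2 fold change 3.001 ± 0.29, adjusted p = 0.000624). In limma with Benjamini-Hochberg adjustment 358 genes passed the threshold, 130 higher and 228 lower. They were 1.68% of all tested genes, the share beside which list counts of 02428 are to be read.

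The ferric-chelate reductase LOC_Os04g48930 fell in 02428 from 11.7 ± 2.47 to 0.513 ± 0.484 FPKM (adjusted p = 0.000779). The helix-loop-helix factor LOC_Os01g72370, annotated to iron homeostasis, fell 5.84-fold (adjusted p = 0.00696). Iron transport and homeostasis, a list drawn after the table was seen, had 1 up and 2 down of 35 (3 up and 4 down adjusted over the list alone) and did not pass camera (adjusted p = 0.791). Metal ion transport had 1 up and 1 down of 47 (2 up and 1 down adjusted over the list alone). The heavy metal-associated domain gene LOC_Os02g32814 rose 6.22-fold to 148 ± 57.6 FPKM (adjusted p = 0.0022), in a list with 1 up and 0 down of 40 (1 up and 1 down adjusted over the list alone). Metallothioneins had 2 up and 0 down of 9 (4 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 0.00475, and adjusted p = 0.66 with an estimated correlation). LOC_Os12g38300 stood at 34.5 ± 23.5 against 3.56 ± 2.696 FPKM (log2 fold change 2.90 ± 0.61, adjusted p = 0.0462). Its call was lost in 9 of 12 fits without 1 library (adjusted p = 0.0671 without CH891 cadmium replicate 1, 0.0747 without CH891 cadmium replicate 2, 0.0729 without CH891 cadmium replicate 3, 0.0689 without CH891 control replicate 2, 0.116 without 02428 cadmium replicate 1, 0.137 without 02428 cadmium replicate 3, 0.126 without 02428 control replicate 1, 0.0547 without 02428 control replicate 2 and 0.127 without 02428 control replicate 3). LOC_Os12g38010 stood at 2.13 ± 0.712 against 0.265 ± 0.253 FPKM (adjusted p = 0.0187), a call also lost in some fits (adjusted p = 0.0675 without 02428 cadmium replicate 3, 0.0827 without 02428 control replicate 2 and 0.0694 without 02428 control replicate 3). Called metallothioneins numbered 0 without 02428 control replicate 2 or 3 or 02428 cadmium replicate 3 and 1 without CH891 control replicate 2, CH891 cadmium replicate 1, 2 or 3, 02428 control replicate 1 or 02428 cadmium replicate 1. Metal ion transport genes called numbered 4 without 02428 cadmium replicate 3, 4 with median-ratio scaling and 4 with quantile normalization.

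The cadmium/zinc ATPase LOC_Os06g48720 stood at 3.97 ± 0.0815 and 3.96 ± 0.344 FPKM with and without cadmium in 02428 (log2 fold change 0.0043). Phytochelatin synthases LOC_Os05g34290 and LOC_Os06g01260 had log2 fold changes of -0.19 ± 0.19 (adjusted p = 0.696) and 0.03 ± 0.17 (adjusted p = 0.971). For the metal transporters LOC_Os07g15370 and LOC_Os03g46470 the values were 0.22 ± 0.16 (adjusted p = 0.58) and -1.50 ± 0.61 (adjusted p = 0.279).

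Heat shock proteins and factors of 02428 had 7 up and 2 down of 102 (14 up and 3 down adjusted over the list alone). LOC_Os02g54140 of the alpha crystallin family rose 17.05-fold, LOC_Os04g01740 rose 23.2-fold to 4.65 ± 0.244 FPKM, and the DnaJ gene LOC_Os03g18870 fell 5.77-fold. Camera placed the list up (adjusted p = 0.0133, and adjusted p = 0.901 with an estimated correlation) with a median of -0.10 and a mean of 0.07, and the median turned to 0.04 under median-ratio scaling. Photosynthetic light reactions had 3 up and 0 down of 47 (10 up and 1 down adjusted over the list alone) and were placed up (adjusted p = 1.21e-05, and adjusted p = 0.66 with an estimated correlation). Photosystem I subunit N LOC_Os12g08770 rose from 143 ± 33.7 to 563 ± 45.3 FPKM (adjusted p = 0.00302). Subunit III LOC_Os03g56670 rose 3.15-fold, a call lost in 4 fits (adjusted p = 0.0738 without 02428 cadmium replicate 1, 0.067 without 02428 cadmium replicate 3, 0.0836 without 02428 control replicate 2 and 0.0521 without 02428 control replicate 3). Class III peroxidases had 1 up and 2 down of 84 (2 up and 2 down adjusted over the list alone) and were placed up (adjusted p = 0.00816, and adjusted p = 0.545 with an estimated correlation), and their member LOC_Os02g14440 fell 8.85-fold. Glutathione S-transferases had 0 up and 0 down of 47, with 8 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 0.0133, and adjusted p = 0.694 with an estimated correlation). Cellulose synthases had 0 up and 0 down of 33, with 6 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 0.0298, and adjusted p = 0.827 with an estimated correlation). NAC factors had 2 up and 2 down of 61 (3 up and 2 down adjusted over the list alone) and were placed up (adjusted p = 0.0298, and adjusted p = 0.827 with an estimated correlation), and LOC_Os02g36880 fell 8.06-fold. Seed storage and lipid transfer proteins had 1 up and 1 down of 79 (4 up and 2 down adjusted over the list alone) and were placed up (adjusted p = 0.0133, and adjusted p = 0.66 with an estimated correlation), and LOC_Os04g52260 rose 5.14-fold. DNA replication and mitosis had 0 up and 0 down of 33, with 4 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone) and was placed down (adjusted p = 0.0478, and adjusted p = 0.987 with an estimated correlation). Single libraries left out ended the calls of glutathione S-transferases (adjusted p = 0.0639 without 02428 cadmium replicate 1 and 0.0509 without 02428 control replicate 2), peroxidases (adjusted p = 0.209 without 02428 cadmium replicate 3), cellulose synthases (adjusted p = 0.0705 without 02428 cadmium replicate 1, 0.0903 without 02428 cadmium replicate 2 and 0.111 without 02428 control replicate 2) and seed storage proteins (adjusted p = 0.143 without 02428 control replicate 3). Called members numbered 13 up and 2 down for heat shock proteins with median-ratio scaling, and for light reactions they were 1 without 02428 control replicate 2 or 02428 cadmium replicate 1 or 3, 5 without CH891 cadmium replicate 1 and 6 with median-ratio scaling. Class III peroxidases called numbered 1 without 02428 control replicate 1 or 2 or 02428 cadmium replicate 1 or 3 and 5 without CH891 cadmium replicate 1. Seed storage proteins called numbered 1 without 02428 control replicate 2 or 02428 cadmium replicate 1 or 2, 4 without 02428 control replicate 1 and 1 with quantile normalization. NAC factors called numbered 1 without CH891 cadmium replicate 2 or 02428 control replicate 1, 2 or 3 and 2 without CH891 control replicate 2 or 02428 cadmium replicate 1, 2 or 3. Calls also ended for NAC factors (adjusted p = 0.0639 without 02428 cadmium replicate 1, 0.0574 without 02428 control replicate 1, 0.0509 without 02428 control replicate 2 and 0.0794 without 02428 control replicate 3) and DNA replication (adjusted p = 0.0505 without CH891 cadmium replicate 2, 0.0577 without CH891 control replicate 3, 0.0917 without 02428 cadmium replicate 1, 0.209 without 02428 cadmium replicate 3, 0.149 without 02428 control replicate 1 and 0.317 without 02428 control replicate 2).

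Cytochrome P450s of 02428 had 3 up and 2 down of 142 (4 up and 2 down adjusted over the list alone), with the 84A1 gene LOC_Os06g24180 12.1-fold higher. The peptidyl-prolyl isomerase LOC_Os04g28420 rose from 0.166 ± 0.0276 to 13.5 ± 2.601 FPKM (adjusted p = 2.64e-05). The thioredoxin LOC_Os02g53400 fell 25.8-fold, and the jmjC-domain gene LOC_Os09g31380 fell 9.805-fold. Antioxidant enzymes had 1 up and 0 down of 43 (2 up and 1 down adjusted over the list alone). Pathogenesis-related proteins had 1 up and 2 down of 48 (2 up and 2 down adjusted over the list alone). Sulfate uptake and assimilation had 0 up and 0 down of 34, with 7 at an unadjusted p under 0.05 (0 up and 1 down adjusted over the list alone). Starch mobilisation had 0 up and 0 down of 12, with 1 at an unadjusted p under 0.05 (0 up and 1 down adjusted over the list alone). Aquaporins had 0 up and 0 down of 24, with 6 at an unadjusted p under 0.05 (0 up and 3 down adjusted over the list alone). Genes annotated as responding to cadmium ion had 3 up and 0 down of 196 (4 up and 2 down adjusted over the list alone). Terpene synthases had 1 up and 0 down of 14 (2 up and 0 down adjusted over the list alone). No member passed limma over all genes or adjusted over the list alone in several lists, given here with the number at an unadjusted p under 0.05 in brackets. They were 10 glutathione and phytochelatin synthesis genes (0), 32 phenylpropanoid and lignin genes (6), 21 jasmonate genes (1), 16 ethylene genes (4), 22 LEA, dehydrin and abscisic acid genes (8), 62 WRKY factors (12) and 10 carbon fixation genes (1). They also included 41 histones (2), 111 cytosolic ribosomal proteins (4), 33 proteasome subunits (0), 29 expansins and xyloglucan enzymes (0), 16 nitrogen genes (0) and 41 ABC transporters (6). Among lists drawn afterwards, the same held for fermentation enzymes (17 tested, 0 at an unadjusted p under 0.05), UDP-glycosyltransferases (37 tested, 4 at an unadjusted p under 0.05) and storage proteins without lipid transfer proteins (3 tested, 1 at an unadjusted p under 0.05). In other fits, P450s called numbered 3 without 02428 control replicate 3 or 02428 cadmium replicate 1 or 2 and 8 with quantile normalization. Pathogenesis-related proteins called numbered 0 without 02428 control replicate 1 or 2 and 1 without 02428 cadmium replicate 1. Genes responding to cadmium ion called numbered 6 without CH891 control replicate 1, 7 with median-ratio scaling and 8 with quantile normalization.

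With an estimated correlation, camera called 0 lists in 02428 (1 at an unadjusted p under 0.05), and fry called 0 (0 at an unadjusted p under 0.05). Calls of glutathione S-transferases, class III peroxidases and seed storage proteins ended under both scalings (adjusted p = 0.0723, 0.0723 and 0.158 with median-ratio scaling). That of NAC factors ended under median-ratio scaling (adjusted p = 0.0723) and that of cellulose synthases under quantile normalization (adjusted p = 0.0792). Uncalled lists placed up with a negative median were jasmonate (-0.11), aquaporins (-0.18), histones (-0.09), antioxidant enzymes (-0.08), proteasome subunits (-0.07), P450s (-0.06), starch (-0.06) and glutathione synthesis (-0.03), all of which but that of aquaporins turned positive under median-ratio scaling. The median of sulfate genes, placed down, turned from -0.13 to 0.01. The same held for lists drawn afterwards of iron transport (-0.18), metal ion transport (-0.09), fermentation (-0.17), heavy metal-associated proteins (-0.12), UDP-glycosyltransferases (-0.05) and the response to cadmium ion, where metal ion transport, heavy metal-associated proteins and the response to cadmium ion turned positive under that scaling. Pathogenesis-related proteins, LEA proteins and carbon fixation were placed up with a positive median and a negative mean (-0.13, -0.19 and -0.13). Metallothioneins, heat shock proteins and light reactions were called in each fit without 1 library. Phenylpropanoid genes (adjusted p = 0.0493 without CH891 cadmium replicate 2, 0.0406 without 02428 cadmium replicate 2 and 0.0169 without 02428 control replicate 1) and expansins (adjusted p = 0.037 without 02428 cadmium replicate 2) were placed up with a library left out and not with all. Camera called 5 lists without 02428 cadmium replicate 1 or 02428 control replicate 2, against 9 with all libraries. The median change of all genes was -0.12, and 0 to 2 decimals under median-ratio scaling, where the excess of falls ended with 256 genes higher and 242 lower. Quantile normalization gave 279 higher and 233 lower. The count of 358 was 167 without 02428 control replicate 2, 233 without 02428 cadmium replicate 1 and 233 without 02428 cadmium replicate 3. Without CH891 control replicate 1 it rose to 535 (169 higher and 366 lower), beside 754 in CH891. The counts of the varieties thus lay closer together without that library.

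**Figure D3:**
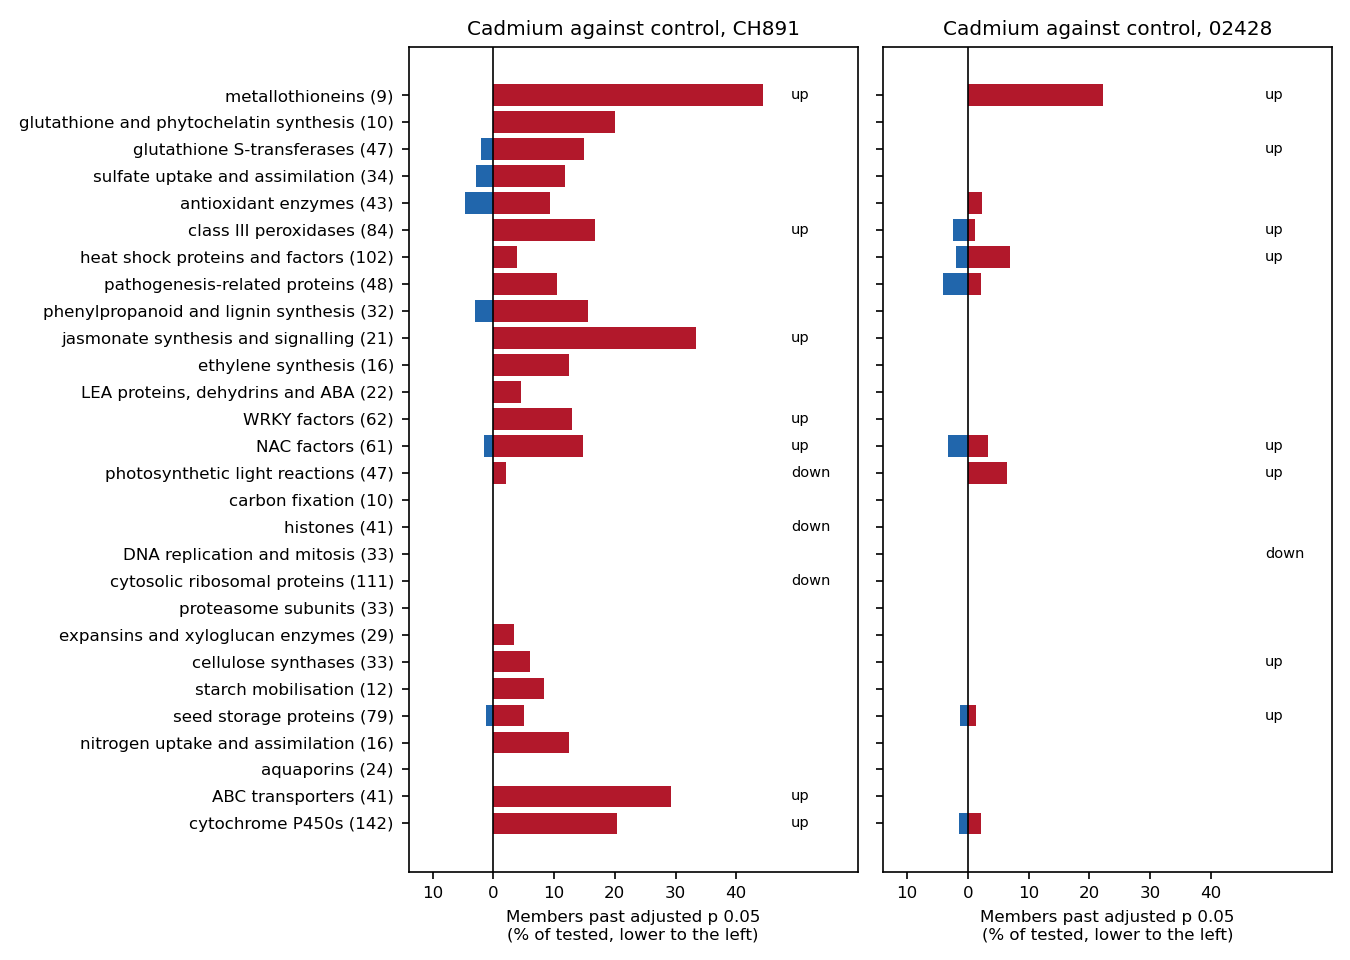
Share of tested members of each gene list past adjusted p 0.05 with cadmium, in percent, higher to the right and lower to the left, for CH891 (left) and 02428 (right), with tested members in brackets and the words up and down for lists that camera placed above or below other genes at the preset correlation. Cytochrome P450s had 29 of 142 members higher in CH891 and 3 in 02428, no placement held with an estimated correlation, and the median of heat shock proteins in 02428 turned from -0.10 to 0.04 with median-ratio scaling.

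The interaction of variety and treatment tested whether the 2 varieties responded differently. P450 72A1 LOC_Os01g43774 changed more in CH891, by 4.23 on the log2 scale (adjusted p = 0.00232). GSTU6 LOC_Os10g38600 did so by 3.83 (adjusted p = 0.00245), and the 12-oxophytodienoate reductase LOC_Os06g11210 by 3.80 (adjusted p = 0.0244). For the cadmium/zinc ATPase LOC_Os06g48720 the difference was 1.63 (adjusted p = 0.00653). Protochlorophyllide reductase A LOC_Os04g58200, an enzyme of chlorophyll synthesis, differed in the other direction by -2.66 (adjusted p = 0.00165). It stood at 171 ± 28.98 FPKM with cadmium and 268 ± 6.39 without in CH891, and at 360.2 ± 35.1 and 90.2 ± 15.9 in 02428.

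In limma with Benjamini-Hochberg adjustment 523 genes differed in response, 458 with the more positive change in CH891 and 65 with the more negative. Of these, 333 were cadmium calls in CH891, 154 in 02428 and 50 in neither. Differences for the metallothioneins LOC_Os12g38300 (1.47, adjusted p = 0.454) and LOC_Os12g38290 (2.15, adjusted p = 0.233) did not pass the test. That of LOC_Os12g38010 did, with 2.17 (adjusted p = 0.00814). The heavy metal-associated domain gene LOC_Os02g32814 had a difference of 0.30 that did not pass (adjusted p = 0.765). Genes that fell in 02428 and differed between varieties were the metal transporter LOC_Os07g15460 by 2.66 (adjusted p = 0.0109), the ferric-chelate reductase LOC_Os04g48930 by 2.97 (adjusted p = 0.00764) and thiC LOC_Os03g47610 by 3.54 (adjusted p = 0.00232). LOC_Os07g15460 stood at 235 ± 14.2 FPKM with cadmium and 294 ± 62.3 without in CH891. The fatty acid hydroxylase LOC_Os10g38940 differed by -2.71 (adjusted p = 0.0112), with 17.8 ± 0.268 against 5.25 ± 0.744 FPKM in 02428.

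In the tests of this difference, cytochrome P450s had 14 up and 0 down of 142 (35 up and 1 down adjusted over the list alone) and were placed up (adjusted p = 0.000252, and adjusted p = 0.724 with an estimated correlation). ABC transporters had 7 up and 0 down of 41 (14 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 5.67e-05, and adjusted p = 0.843 with an estimated correlation). WRKY factors had 1 up and 0 down of 62 (11 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 0.0263, and adjusted p = 0.843 with an estimated correlation). Jasmonate synthesis and signalling had 4 up and 0 down of 21 (7 up and 0 down adjusted over the list alone) and was placed up (adjusted p = 0.0423, and adjusted p = 0.724 with an estimated correlation). Metallothioneins had 1 up and 0 down of 9 (1 up and 0 down adjusted over the list alone) and were placed up (adjusted p = 0.0263, and adjusted p = 0.843 with an estimated correlation). Photosynthetic light reactions had 1 up and 1 down of 47 (1 up and 4 down adjusted over the list alone) and were placed down (adjusted p = 3.24e-10, and adjusted p = 0.724 with an estimated correlation), with a median of -0.61 and a mean of -0.07. Heat shock proteins had 2 up and 3 down of 102 (4 up and 6 down adjusted over the list alone) and were placed down (adjusted p = 0.0302, and adjusted p = 0.922 with an estimated correlation) with a median of 0.15, which turned to -0.16 under median-ratio scaling. Histones had 0 up and 0 down of 41, with 1 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone) and were placed down (adjusted p = 0.0263, and adjusted p = 0.885 with an estimated correlation), with a median of 0.01 that turned to -0.33 under that scaling. Seed storage proteins had 2 up and 2 down of 79 (2 up and 3 down adjusted over the list alone) and were placed down (adjusted p = 0.0423, and adjusted p = 0.724 with an estimated correlation), with a median of 0.21 that turned to -0.02. P450s, ABC transporters and light reactions were called in each fit without 1 library. Calls that ended without single libraries were those of WRKY factors (adjusted p = 0.0722 without 02428 cadmium replicate 2 and 0.0735 without 02428 control replicate 3), metallothioneins (adjusted p = 0.0597 without CH891 cadmium replicate 3, 0.058 without CH891 control replicate 1 and 0.0722 without 02428 cadmium replicate 2), heat shock proteins (adjusted p = 0.078 without CH891 cadmium replicate 1, 0.0646 without CH891 cadmium replicate 3, 0.0556 without CH891 control replicate 3 and 0.0529 without 02428 cadmium replicate 1) and histones (adjusted p = 0.0646 without CH891 cadmium replicate 1, 0.143 without 02428 cadmium replicate 3 and 0.167 without 02428 control replicate 3). Jasmonate lost its call often (adjusted p = 0.347 without CH891 cadmium replicate 1, 0.142 without CH891 cadmium replicate 2, 0.237 without CH891 cadmium replicate 3, 0.0866 without CH891 control replicate 2, 0.119 without CH891 control replicate 3, 0.071 without 02428 cadmium replicate 2, 0.104 without 02428 cadmium replicate 3, 0.187 without 02428 control replicate 1 and 0.0735 without 02428 control replicate 3), and so did seed storage proteins (adjusted p = 0.267 without CH891 cadmium replicate 2, 0.0646 without CH891 cadmium replicate 3, 0.462 without CH891 control replicate 1, 0.0683 without CH891 control replicate 3, 0.0543 without 02428 cadmium replicate 1, 0.0859 without 02428 cadmium replicate 3 and 0.216 without 02428 control replicate 3). Called with a library left out, and not with all, were ribosomal proteins (adjusted p = 0.00187 without CH891 cadmium replicate 3, 0.014 without CH891 control replicate 1 and 0.0081 without 02428 control replicate 2), carbon fixation (adjusted p = 0.0409 without CH891 cadmium replicate 1) and antioxidant enzymes (adjusted p = 0.0276 without 02428 control replicate 1), all placed down, and DNA replication, placed up (adjusted p = 0.0185 without CH891 cadmium replicate 1). Camera called 5 lists without 02428 control replicate 3, against 9 with it. Called P450s numbered 8 without CH891 cadmium replicate 3 and 9 without CH891 cadmium replicate 2. ABC transporters called numbered 2 without CH891 cadmium replicate 3, 3 without CH891 cadmium replicate 2 and 4 without 02428 control replicate 1 or 3 or 02428 cadmium replicate 2 or 3. Jasmonate genes called numbered 0 without CH891 cadmium replicate 2 or 3, 2 without CH891 cadmium replicate 1, 02428 control replicate 3 or 02428 cadmium replicate 2 or 3 and 2 with quantile normalization. Called light reaction genes numbered 1 without CH891 control replicate 1 or 2, CH891 cadmium replicate 2 or 3, 02428 control replicate 1 or 2 or 02428 cadmium replicate 2 or 3 and 4 without CH891 cadmium replicate 1. Heat shock proteins called numbered 3 without CH891 control replicate 2 or 3, CH891 cadmium replicate 3, 02428 control replicate 2 or 3 or 02428 cadmium replicate 1 and 8 with quantile normalization. Seed storage proteins called numbered 1 without CH891 control replicate 1, 2 or 3, 02428 control replicate 2 or 02428 cadmium replicate 2 and 2 without CH891 cadmium replicate 1, 2 or 3, 02428 control replicate 1 or 3 or 02428 cadmium replicate 1 or 3. For metallothioneins, histones and WRKY factors, with 0 or 1 members called, the numbers moved by at most 2 members. Uncalled lists placed down with a positive median were phenylpropanoid (0.25), ethylene (0.06), carbon fixation (0.16), ribosomal (0.19), expansin (0.18) and cellulose synthase genes (0.13), with terpene synthases (0.26) and UDP-glycosyltransferases (0.45) among lists drawn afterwards, and all of these medians but that of UDP-glycosyltransferases turned negative under median-ratio scaling. Antioxidant enzymes were placed down with a positive mean (0.03).

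The median difference of all genes was 0.27, and -0.01 under median-ratio scaling, where 317 genes were higher and 138 lower and the calls of histones and seed storage proteins ended (adjusted p = 0.171 and 0.584). Quantile normalization gave 277 higher and 145 lower. The count of 523 was 215 without CH891 cadmium replicate 2, 209 without CH891 cadmium replicate 3, 329 without 02428 cadmium replicate 2 and 331 without 02428 cadmium replicate 3. It was 334, 332 and 314 without 02428 control replicates 1, 2 and 3 in turn, and 374 without CH891 control replicate 1.

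Genes called in both varieties included the heavy metal-associated domain gene LOC_Os02g32814 and the metallothionein LOC_Os12g38300, both higher with cadmium. In all, 28 genes rose in both varieties, where independent lists would share 5.61, and 3 fell in both, where they would share 0.663. Another 11 rose in CH891 and fell in 02428 (9.84 for independent lists), and 1 did the reverse (0.378). The 2 comparisons use different libraries. Changes had a Pearson r of 0.125 across the tested genes, which are not independent replicates. The 31 genes with 1 direction in both were 59 under median-ratio scaling, 57 under quantile normalization, and 18 without 02428 control replicate 2.

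The varieties were also compared within each treatment. Phenylalanine ammonia-lyase LOC_Os12g33610, the entry enzyme of phenylpropanoid synthesis, stood at 1.84 ± 0.0311 FPKM in CH891 controls and 77.6 ± 7.03 in 02428 controls (log2 difference -4.79 ± 0.23, adjusted p = 2.11e-07). The helix-loop-helix factor LOC_Os04g35010 was 42.5-fold lower and the acyltransferase LOC_Os02g37800 57.7-fold lower in CH891 controls. The MYB factor LOC_Os02g46940 was higher in CH891, with 9198, 2232 and 1397 FPKM in its controls and 57.6, 54.9 and 7.93 in those of 02428. LOC_Os01g35330, described as a circumsporozoite protein precursor, stood at 83.9 ± 31.6 FPKM in CH891 controls and 0.607 ± 0.548 in 02428 controls. With cadmium, the nicotianamine synthase LOC_Os03g19427, which makes a metal chelator, stood at 829 ± 567 FPKM in CH891 and 14.9 ± 13.5 in 02428 (adjusted p = 0.00255). The BURP-domain gene LOC_Os05g12640 was 50.5-fold lower in CH891 with cadmium. Whether CH891 reads of such single genes mapped less well to the reference was not tested. In controls limma with Benjamini-Hochberg adjustment called 1299 genes higher and 3510 lower in CH891, and with cadmium 2825 higher and 2508 lower, an excess that turned under quantile normalization (3035 higher and 3127 lower), without CH891 cadmium replicate 2 (1874 and 2074) and without 02428 cadmium replicate 3 (2068 and 2082). The median difference of all genes in controls was -0.20, and 0.02 under median-ratio scaling, where 2452 genes were higher and 2664 lower. Quantile normalization gave 2548 higher and 2618 lower in controls, and without CH891 control replicate 1 the numbers were 1787 and 2742.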

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

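The test of depth in the CH891 pattern and the tests of mapping and of scaling in the variety pattern were chosen only after the result was seen.

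The genes below stood out because their responses to cadmium passed the test of the difference between varieties. Camera at the preset correlation also placed 9 lists on that difference, and with an estimated correlation 0 (lowest adjusted p = 0.724, 1 at an unadjusted p under 0.05), while fry called 8. The median difference of all genes, 0.27 as deposited, can add to the calls of fry, which was not run on scaled values. Median log2 differences of the 9 lists placed by camera were 1.36 for metallothioneins, 0.34 for jasmonate, 0.59 for WRKY factors, 0.63 for ABC transporters and 0.67 for P450s. They were -0.61 for photosynthetic light reactions, 0.15 for heat shock proteins, 0.0097 for histones and 0.21 for seed storage proteins, all 4 placed down at the preset correlation and not with an estimated one. Under median-ratio scaling the calls of histones and seed storage proteins ended (adjusted p = 0.171 and 0.584), and the medians of heat shock proteins, histones and seed storage proteins turned to -0.16, -0.33 and -0.02. More positive responses in CH891 were found for the P450s LOC_Os01g43774 (4.23) and LOC_Os01g43750 (3.79), the glutathione S-transferases LOC_Os10g38600 (3.83) and LOC_Os01g72150 (2.76), and the metallothionein LOC_Os12g38010 (2.17). So it was for the ABC transporter LOC_Os01g50160 (2.52), the ATPase LOC_Os06g48720 (1.63), the cysteine synthase LOC_Os02g12900 (2.55), the peroxiredoxin LOC_Os07g44440 (2.46) and LOC_Os08g36630 (1.84). The 12-oxophytodienoate reductase LOC_Os06g11210 (3.80), the laccase LOC_Os11g42200 (2.70), the oxidase homolog LOC_Os04g10350 (1.98), WRKY1 LOC_Os01g14440 (2.25) and the nitrite reductase LOC_Os05g42350 (1.55) had the same direction. Among genes that fell in 02428 were LOC_Os07g34570 (4.96), thiC LOC_Os03g47610 (3.54), the ferric-chelate reductase LOC_Os04g48930 (2.97), the metal transporter LOC_Os07g15460 (2.66) and the helix-loop-helix factor LOC_Os01g72370 (2.66). Others were the jmjC gene LOC_Os09g31380 (3.47), the thioredoxin LOC_Os02g53400 (2.96), the DnaJ gene LOC_Os03g18870 (3.02) and the NAC gene LOC_Os02g36880 (2.52). The annotation ties LOC_Os09g31380 to circadian rhythm, as it does the MYB factor LOC_Os08g06110. The labels give no time of day, so for such genes collection time and an effect of cadmium cannot be told apart.

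More negative responses in CH891 were those of the MYB factor LOC_Os08g06110 (-3.83), the fatty acid hydroxylase LOC_Os10g38940 (-2.71), protochlorophyllide reductase LOC_Os04g58200 (-2.66) and photosystem I subunit N LOC_Os12g08770 (-2.65). Likewise lower were the lipid transfer gene LOC_Os04g52260 (-2.41), the glutathione S-transferase LOC_Os03g04240 (-2.25), the isomerase LOC_Os04g28420 (-1.95) and the heat shock gene LOC_Os04g01740 (-1.83). In 3 genes the fitted difference rests on libraries listed at 0. These were LOC_Os08g37810 (-3.73) and LOC_Os10g40420 (-3.56), listed at 0 in all libraries other than the CH891 controls (8.89, 16.1 and 12.7 FPKM and 12.7, 10.2 and 9.74 FPKM), and LOC_Os05g45710 (-3.09), listed at 0 in CH891 with cadmium and at 4.52, 11.1 and 12.2 FPKM without.

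Other splits of the libraries were counted beside each count of calls. For the difference of responses, 2 of 100 drawn splits of treatment within both varieties called at least 523 genes, the real split included. The other of them called 904 genes and is the real split with cadmium and control exchanged in 1 variety. It tests the sum of the responses and so follows a structure of the samples. Mixing the treatments of a variety also removes its cadmium response, so low counts there were fixed in advance. These splits therefore test for any response and do not decide whether the responses of the varieties differ. For lists on that difference, 9 of 100 splits called at least the real 9, and up to 14, so chance was not excluded. The 31 genes with 1 direction in both varieties were reached by 1 of 100 splits, the real one, with 12 in the highest other. A variety whose treatments were mixed had at most 16 calls in CH891 and 21 in 02428, too few to reach 31. The 12 are the genes with opposite directions, counted with cadmium and control exchanged in 1 variety. So these splits do not test whether the directions agree. For 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 982 and 16 genes in CH891, 358 and 21 in 02428, 4809 and 5 between varieties in controls, and 5333 and 8 with cadmium. For lists they were 10 and 15 in CH891, and 9 and 7 in 02428. In CH891, 2 of 10 splits, the real one included, called at least 10 lists. A split that mixed the treatments thus called more lists with camera at the preset correlation than the real one. The number of lists called in CH891 is therefore not told apart from chance.

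In CH891, 93.7% of called genes were higher with cadmium. Low values of CH891 control replicate 1 are argued against as the whole cause by 81.4% higher without it, and scaling by 73.2% higher with median-ratio scaling, both above the limit of 65% set for them, though each share was lower than 93.7%. Greater depth of the cadmium libraries stays open. In 02428, where they were also deeper than controls, 36.3% of called genes were higher, under the limit of 50% set for it. That share was above the limit with median-ratio scaling (51.4%) and quantile normalization (54.5%). A larger number of induced than repressed genes in CH891 also stays open as a hypothesis, and part of the 93.7% may come from scaling and from that library.

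Among controls, 27.0% of genes called between varieties were higher in CH891 and the others lower. Poorer mapping of CH891 reads to the reference would be shared by both treatments, and 47.0% were lower with cadmium. That share also moves with the median difference of all genes, 0.07 with cadmium, so it does not decide on mapping. Among controls without CH891 control replicate 1 the share lower was 60.5%, above the limit of 55% set for that library as the whole cause. With median-ratio scaling it was 52.1%, but this scaling itself moves the median difference of all genes from -0.20 to 0.02, which brings a near-even split whatever the cause. Scaling of the control libraries, poorer mapping of CH891 reads and a biological difference between the varieties therefore cannot be told apart. The biological difference stays untested.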

How the results depend on the processing

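Leaving out genes with a 0 beside a value of 5 or more, and list members under the scalings or without 1 library, were chosen after seeing the data. The former gave 1024 genes in CH891 and 413 in 02428. Of 143 calls of named genes 80 held under every alternative run on them and 0 reversed, where not every call was tested under each alternative. In fits without 1 library 1432 such calls held and 248 were lost. In fits of only the groups compared 84 held and 43 were lost. At FPKM of at least 5, with fewer genes tested, counts were 460 in CH891, 156 in 02428, 202 for the difference, 2054 and 2552 between varieties in controls and with cadmium, and 17 shared. Fits of only the groups compared, with fewer samples, gave 459 in CH891, 229 in 02428 and 17 shared. A fold change of at least 2 left 643 in CH891 and 2899 and 3324 between varieties. Median-ratio scaling and quantile normalization gave 59 and 57 shared genes, and 5 and 5 lists in 02428. A pseudocount of 0.1 gave 327 genes and 4 lists for the difference, and no filter gave 3 lists in 02428. For these settings the cause was not tested. With an estimated correlation 0 lists were called in CH891, 02428 and the difference (3, 1 and 1 at an unadjusted p under 0.05), and fry called 12, 0 and 8. Deviations of same-numbered libraries correlated at -0.04 to 0.06 over 18 pairs, 0 above 0.1, and 3 of 12 libraries correlated best with their own number, so the numbers do not pair them. A replicate block gave 334 genes for the difference, 768 in CH891 and 249 in 02428. Without 1 library, genes numbered 393 to 919 in CH891, 167 to 535 in 02428, 209 to 429 for the difference, 3714 to 4670 and 3948 to 6179 between varieties and 18 to 46 shared. Lists numbered 5 to 13 in CH891, 5 to 10 in 02428 and 5 to 10 for the difference. They were 5 in CH891 without CH891 cadmium replicate 1, in 02428 without 02428 cadmium replicate 1 or 02428 control replicate 2, and for the difference without 02428 control replicate 3. Log2 fold changes of 3 uncalled genes turned sign, from -0.254 to 0.051 for LOC_Os05g34290 in CH891, from -0.044 to 0.143 for LOC_Os06g01260 in 02428, and from -0.053 to 0.044 for LOC_Os06g48720 in 02428. Depth is unknown, and of simulated log2 changes of 1 in genes that were not low, 20.5% were recovered in CH891 and 30.5% in 02428.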

Other observations

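The pathway tests, the choice of clock genes and the test of scaling on them came only after the result was seen, and the rule for reading the test on other circadian genes was changed after its value was seen.

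In CH891 with cadmium, brassinosteroid biosynthesis, the pathway of a steroid hormone of plants, was placed up, and there 12 of 45 genes rose and 1 fell (adjusted p = 6.31e-06, and adjusted p = 0.993 with an estimated correlation). In alpha-linolenic acid metabolism, which feeds jasmonate synthesis, 11 of 66 genes rose and 0 fell (adjusted p = 0.00275, and adjusted p = 0.993 with an estimated correlation). In phenylpropanoid biosynthesis 34 of 278 genes rose and 0 fell (adjusted p = 0.00713, and adjusted p = 0.993 with an estimated correlation). In plant-pathogen interaction 58 of 823 genes rose and 0 fell (adjusted p = 0.0126, and adjusted p = 0.993 with an estimated correlation), and in protein processing in the endoplasmic reticulum 34 of 387 genes rose and 1 fell (adjusted p = 0.0105, and adjusted p = 0.993 with an estimated correlation). Photosynthesis was placed down, and there 1 of 61 genes rose and 1 fell (adjusted p = 0.00275, and adjusted p = 0.993 with an estimated correlation). In 02428, antenna proteins of photosynthesis were placed up with a median of 0.49, and 1 of 15 genes rose and 0 fell (adjusted p = 0.000761, and adjusted p = 0.994 with an estimated correlation). Of 130 pathways, camera placed 21 up and 3 down in CH891, 10 up and 1 down in 02428, and 3 up and 3 down for the difference. With an estimated correlation camera placed 0, with 5, 1 and 3 at an unadjusted p under 0.05, and fry called 14, 0 and 4.

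Of 126 tested genes in the circadian rhythm pathway, 9 were called in 02428, with 1 higher and 8 lower with cadmium, and 5 in CH891. These shares were 7.14% against 1.68% of all tested genes in 02428, and 3.97% against 4.60% in CH891. As a whole the pathway did not pass camera in 02428 (adjusted p = 0.751). GIGANTEA LOC_Os01g08700, a component of the plant clock, fell from 134 ± 40.8 to 25.7 ± 3.03 FPKM in 02428 (adjusted p = 0.00189). In CH891 it stood at 182 ± 43.4 with and 167 ± 30.6 without cadmium (difference of responses, adjusted p = 0.0097). Of 6 tested MYB genes that share a KEGG identifier, 2 were called. LOC_Os08g06110 rose by 3.001 on the log2 scale and LOC_Os04g49450 fell by 1.10. The F-box gene LOC_Os11g34460 fell by 2.12, the response regulator LOC_Os02g40510 fell by 1.18, and the B-box gene LOC_Os02g49230 fell by 1.60. Other B-box genes were LOC_Os06g16370, which fell by 1.32, and LOC_Os06g19444, which fell by 1.96. The 5 genes called in CH891 were others, but their share was near that of all genes. So few calls do not show that the varieties changed different clock genes. They were the dof genes LOC_Os04g47990 and LOC_Os04g58190, which rose by 1.51 and 0.90, LOC_Os01g43230, which fell by 0.66, the TCP-domain gene LOC_Os06g12230, listed at 0 with cadmium and at 4.45, 7.85 and 8.24 FPKM without, and the bZIP factor LOC_Os06g41770, up from 5.84 ± 0.669 to 29.1 ± 4.44 FPKM (adjusted p = 5.91e-05).

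Scaling is argued against for the clock genes of 02428 as a set, since 8 of 9 kept call and direction with median-ratio scaling. The remaining gene, LOC_Os10g40740, went from -1.18 ± 0.25 to -1.03 ± 0.23 (adjusted p = 0.0545), a smaller change with a like error. A candidate explanation is that treated and control seedlings of 02428 were collected at different times of day. Circadian genes outside the pathway were called at 5.56% (2 of 36), percentile 90.8 among 10000 random lists matched on expression, which is under the limit of 95 set beforehand and would by that limit exclude the explanation. The limit was judged too coarse only afterwards, because with 36 genes 2 calls equal the 95th percentile of the random lists (5.56%), and since the labels give no time of day, collection time and an effect of cadmium on the clock cannot be told apart.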
